A study of Mus musculus with 6 samples.

How the data were processed

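RNA from mouse trophoblast stem cells was hybridised to Affymetrix whole-genome mouse expression arrays. There were 6 arrays, 1 for each of 3 cell lines (EGFP, L5 and LacZ) in each of 2 media (TS and TX). The deposited values were on a log2 scale and had been produced with RMA, per the submitters' processing notes, which gave no version. RMA combines background correction, quantile normalization between arrays and a summary of the probes of each probe set, so the arrays had closely matching distributions before any test. Medians of the arrays lay between 5.48 and 5.54, and single values between 1.42 and 13.89. Scanner files were not used here.

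Of 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 had none in the table used. Each of 18194 genes was represented by its brightest probe set by the mean of the 6 arrays, and 9012 genes had more than 1 to choose from. No filter was set on dim probe sets. Of 589 entries in the 27 gene lists, 534 could be measured, and genes such as Hmgcr, Ldlr, Prl3d1, Gcm1 and Syna were unnamed here. Chromosomes and gene order came from the RefSeq gene table of assembly GRCm38.p6. Start coordinates were used only to order the genes, and genes without one were left out of the chromosome comparison.

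Media were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the cell line as a block, two-sided, and with Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. Residual degrees of freedom were 2 and the prior added 3.50. The pairing came from the cell line named in the labels. Deviations from the group means correlated across genes at 0.299, 0.327 and 0.411 for the 3 pairs of one line, and below 0 for every pair of different lines. Taking off the group means pushes the values between lines below 0, so those are no separate evidence for the pairing. Cell lines were compared in the same fit by a moderated F test and then pair by pair. Each combination of line and medium had 1 array, so a difference between lines in their response to the medium could not be tested. Nothing in the labels said whether arrays came from separate cultures, and p-values measure the spread between these arrays. The number of arrays limits the precision.

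The gene lists, the design, the rule for naming genes and most alternatives were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. The rule named the 10 genes with the largest rise and the 10 with the largest fall past the threshold. Where fewer passed, places were filled by the smallest unadjusted p among genes that moved at least 2-fold the same way in all 3 lines. It also named the 4 members of each list with the smallest unadjusted p, a set of trophoblast markers, and, for the lines, the genes most apart from the other lines and the sex-linked genes. Other alternatives were a second quantile normalization, median centring, filters at the 25th percentile and the median of mean signal, every named probe set, the mean of a gene's probe sets, an intensity trend with robust moderation, no line block, and leaving out each line or array. Leaving out chromosomes 1, 8, 11 and 14 was added after their values were seen. It also removed the called genes and list members that lie there, so a lower count or a lost call is no test of chromosome shifts.

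The fits were tested on simulated data with 200 changed genes among 18194, with the spread taken from these arrays. For the medium, 39.7% of genes changed by 1 log2 unit were recovered, 94.8% of those changed by 2, and on average 8.25 of 174.6 called genes were false. Every changed gene was given the same change in all 3 lines. These shares therefore do not hold for genes whose change varied between lines. In the real data Ddx4 (2.88) and Lncenc1 (-3.06), both picked after their values were seen, missed the threshold. In 20 simulated sets, a list of fatty acid genes shifted by 0.75 was called 20 times with the preset correlation and 0 times with an estimated one. A count of 0 with an estimated correlation thus excludes no shift of that size. The simulated noise was independent between genes, so these sets cannot show that calls with the preset correlation are sound where genes vary together. In the real data the estimated correlation was 0.52 for the cholesterol list and 0.59 for the ATF4 list. It was -0.0055 for the fatty acid list and -0.021 for a list of germline genes described below, both under the preset 0.01. These 2 lists lost their calls as well, so a high correlation between genes does not account for those losses. For the lines, the F test recovered 83.5% of genes changed by 2 log2 units in 1 line and 99% of those changed by 4. That change was the same in both media. A shift of 0.25 on 1 chromosome was found in 5 of 5 simulated pairs of arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.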

Results

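Trophoblast stem cells are derived from the outer lineage of the early mouse embryo, self-renew in the presence of FGF4, and can form the cell types of the placenta. Expression was profiled in 3 such lines, EGFP, L5 and LacZ, each grown in TS and in TX medium. The labels give only these names. From what is known of the study, and not from the labels, TS is taken to be the conventional medium with serum and fibroblast-conditioned medium, and TX a defined medium without serum. The question was how far the transcriptome of the cells differs between these media. Each medium was represented by 3 arrays, 1 per line, and each line by 2.

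Pairs of arrays correlated across genes at Pearson's r between 0.967 and 0.985. The mean r was 0.981 for arrays of one line, 0.980 for arrays of one medium and 0.974 for pairs that shared neither. Genes are not independent replicates, so these values are descriptive. Over genes, the cell line took 47.6% of the sum of squares, the medium 29.1% and the residual 23.3%, where degrees of freedom alone would give 40%, 20% and 40%.

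In TX medium 23 genes were higher and 1 was lower than in TS medium. The largest fitted rise was in Ripk3, a kinase of the necroptosis pathway, at 3.71 ± 0.13 (log2, SE, n = 3 lines; limma, adjusted p = 0.00558). Its mean signal was 5.41 ± 0.39 in TS and 9.12 ± 0.30 in TX (SD, n = 3). Slc7a3, a transporter of cationic amino acids, rose by 2.90 ± 0.14 (SE), and the cysteine protease Ctsh by 2.67 ± 0.12, both at adjusted p = 0.0106. Meioc and Syce1, which act in meiosis, rose by 2.81 ± 0.25 and 2.76 ± 0.24, both at adjusted p = 0.0472. The other genes with the largest rises were Itih5 (2.39), Plekhd1 (2.32), Tac1 (2.22), which encodes the precursor of substance P, Ctsa (2.17), a lysosomal carboxypeptidase, and Lipo3 (2.12). Another probe set of Ctsa (-0.11) and another of Tac1 (0.08) did not show the rise. Other probe sets of Ctsh (2.53) and Itih5 (1.16 and 1.95) did. RMA gives no detection call, and the TS means of Ripk3, Ctsh (5.26), Meioc (2.86), Syce1 (4.45), Itih5 (4.42), Plekhd1 (4.87) and Tac1 (4.61) lay below the array medians of 5.48 to 5.54, with Slc7a3 (5.81) and Lipo3 (5.85) just above them. These signals were not shown to exceed background, so the sizes and ranks of the rises are uncertain. The fatty acid desaturases Fads2 and Fads1 rose by 1.83 ± 0.12 and 1.55 ± 0.14.

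**Figure D1:**
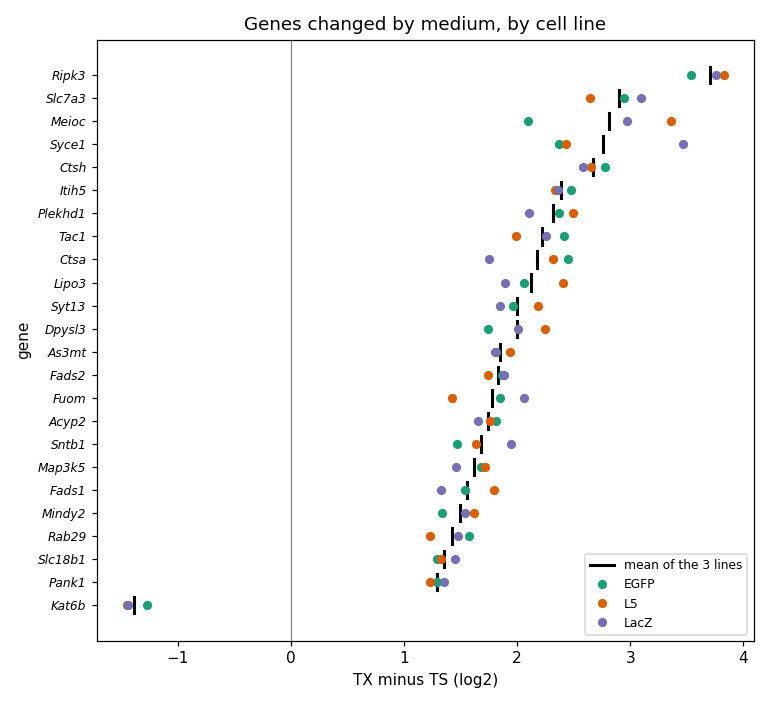
TX minus TS on the log2 scale (x axis) for each of the 24 genes past the threshold (y axis), with a point per cell line and a black bar at the mean of the 3 lines. Every gene moved the same way in all 3 lines, from Ripk3 at 3.71 down to Kat6b at -1.39.

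The gene that was lower was Kat6b, a histone acetyltransferase, which fell by 1.39 on the log2 scale (SE 0.12, adjusted p = 0.0472 by limma). Its other probe sets, dim at 4.07 or below on every array, gave -0.16 and -0.39. The 9 genes with the next smallest p among those lower in all 3 lines and at least 2-fold lower on average missed the threshold, at adjusted p from 0.0546 to 0.0739. They included the RNA-binding protein gene Igf2bp3 (-1.52 ± 0.16), Laptm5 (-1.23 ± 0.13), Rab11fip2 (-1.23 ± 0.13), the hedgehog ligand Dhh (-1.09 ± 0.12), Tph1 (-1.28 ± 0.14), which encodes a tryptophan hydroxylase, and the immediate early gene Fos (-1.31 ± 0.16). The others were Casq1 (-1.11), Fam217b (-1.18) and Plcxd2 (-1.23). The fall of Laptm5 rests on 1 probe set: its other probe sets gave -0.04 to -0.52, and none of them was lower in all 3 lines. Dhh and Tph1 were near the array median or below it in TX, at 5.49 and 5.14, and the sizes of their falls are uncertain. Larger fitted falls, with larger p, were among the other genes lower in every line, such as Lncenc1 (-3.06, adjusted p = 0.0770, with a dim TX mean of 5.33) and Sdc1 (-1.63, adjusted p = 0.104), both named after their values were seen.

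By size alone, 93 genes differed at least 2-fold the same way in every line, 77 higher and 16 lower in TX, and all 24 genes past the threshold were among them. Within a line, 854 genes differed at least 2-fold in EGFP, 676 in L5 and 524 in LacZ. Of all genes, 37.2% had the same sign in all 3 lines, against 25% by chance. The count of 24 moved when a line was left out, although all 24 genes kept their sign each time. A fit without a line also has fewer residual degrees of freedom, so lost power and dependence on that line cannot be told apart. Without EGFP 1 gene passed, without L5 34 and without LacZ 0 (limma, with 1742 genes at an unadjusted p under 0.05), and without the line block it was 11. Ripk3 and Kat6b lie on chromosome 14, Meioc and Acyp2 on 11 and Rab29 on 1, whose genes also differed as a group between arrays. Between media within a line, only chromosome 14 in L5 had a median of at least 0.15 in size. Without chromosomes 1, 8, 11 and 14, the 19 called genes that remained all passed. That count follows from removing the others and does not test the chromosome shifts.

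The genes that mark the stem cell state showed no change past the threshold. Cdx2 differed by -0.44 (95% interval -0.91 to 0.04), Eomes by 0.18 (-0.36 to 0.72), Elf5 by 0.10 (-0.24 to 0.43), Esrrb by -0.15 (-0.75 to 0.46), Tfap2c by 0.04 (-0.30 to 0.38) and the FGF receptor gene Fgfr2 by 0.13 (-0.27 to 0.52). Changes up to the bounds of these intervals are not excluded. Of the 24 trophoblast stem cell markers, 0 passed over all genes and 1, Satb1 (-1.11 ± 0.18), when adjusted over the list alone. In all 3 lines 8 were lower and 2 higher. The other members that the rule named, Lin28a (-1.06), Bmp4 (-0.90) and Tet1 (-0.71), had lower means in TX but did not pass. The list had a median of -0.09 (camera, adjusted p = 0.0833), and 4 of 13 alternatives called it lower in TX, with adjusted p from 0.0026 to 0.636 over all of them. Tpbpa, a spongiotrophoblast marker, differed by 0.75 ± 0.22 (limma, adjusted p = 0.266).

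Genes of cholesterol synthesis and uptake were higher in TX as a group. All 20 measured members were higher in all 3 lines, with a median of 1.04 (2.06-fold). Lss, which closes the sterol ring, differed by 1.70 ± 0.16, the mevalonate pathway kinase Pmvk by 1.47 ± 0.15, and the late enzymes Nsdhl and Dhcr7 by 1.49 ± 0.16 and 1.15 ± 0.12. Over all genes 0 of 20 passed, and 18 when adjusted over the list alone. The list passed camera (adjusted p = 5.83e-21), but not with an estimated correlation (adjusted p = 0.636 with an estimated correlation). Genes of fatty acid synthesis had a median of 0.78, and 15 of 20 were higher in every line. Fads1 and Fads2 passed over all genes, and 13 genes when adjusted over the list alone, among them the desaturase gene Scd1 (1.42 ± 0.17) and the acyl-CoA ligase gene Acsl3 (1.06 ± 0.14). Camera gave an adjusted p of 1.12e-12, fry 0.0362, and camera an adjusted p = 0.398 with an estimated correlation.

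The amino acid response controlled by ATF4 was also higher in TX, with all 23 members above 0 on average, 13 of them in every line, and a median of 0.72 (camera, adjusted p = 5.49e-10; adjusted p = 0.636 with an estimated correlation). Its medians were 0.05 in EGFP, 1.29 in L5 and 0.94 in LacZ. Atf5 differed by 1.49 ± 0.16, the serine synthesis gene Psat1 by 0.90 ± 0.23 and Ddit4 by 0.72 ± 0.15, and 8 members passed when adjusted over the list alone, 0 over all genes. NRF2 target genes and selenoproteins had a median of 0.30 over 22 genes (camera, adjusted p = 0.000168; adjusted p = 0.636 with an estimated correlation). In this list Selenop (0.87 ± 0.16) and Selenow (0.74 ± 0.16) passed when adjusted over the list alone, and 0 over all genes.

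Iron and metal handling genes shifted up with a median of 0.21 over 14 genes (camera, adjusted p = 0.0200; adjusted p = 0.636 with an estimated correlation). The metal-binding metallothioneins Mt1 (1.71 ± 0.26) and Mt2 (1.36 ± 0.24) and the zinc exporter Slc30a1 (0.94 ± 0.19) were among 4 members that passed when adjusted over the list alone, with 0 over all genes. Mt1 and Mt2 lie on chromosome 8 and Slc30a1 on chromosome 1. Without chromosomes 1, 8, 11 and 14 the adjusted p by camera was 0.681, in a range of 0.00387 to 0.681 over the alternatives. Without EGFP it was 0.129. Leaving out these chromosomes removed those members, so the lost call does not show that chromosome shifts raised the list. Between media within a line, only chromosome 14 in L5 had a median of at least 0.15 in size.

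**Figure D2:**
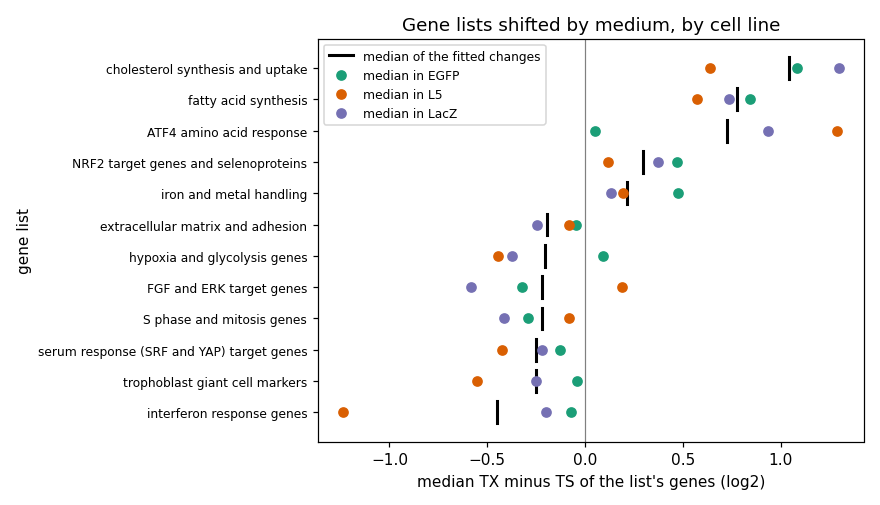
Median TX minus TS on the log2 scale (x axis) of the genes in each of the 12 lists called by camera (y axis), with a point per cell line and a black bar at the median of the fitted changes. Cholesterol genes reached 1.30 in LacZ, and interferon response genes -1.24 in L5.

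Of the 7 lists that shifted down in TX, genes of S phase and mitosis had 21 of 24 members below 0 and a median of -0.22 (camera, adjusted p = 5.13e-05; adjusted p = 0.636 with an estimated correlation). No member passed over all genes or over the list alone, with Aurkb at -0.54 ± 0.13, Ccne1 at -0.49 ± 0.12 and Cdk1 at -0.36 ± 0.12. Target genes of SRF and YAP, which respond to serum, had a median of -0.25 over 25 genes (camera, adjusted p = 8.24e-05; adjusted p = 0.636 with an estimated correlation). Fos, the actin crosslinker gene Flna (-1.01 ± 0.12) and the tropomyosin gene Tpm2 (-0.73 ± 0.15) passed when adjusted over the list alone, and 0 over all genes.

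Interferon response genes had a median of -0.45 over 21 genes (camera, adjusted p = 0.00226; adjusted p = 0.645 with an estimated correlation). By line the median was -0.07 in EGFP, -1.24 in L5 and -0.20 in LacZ, and Usp18 differed by -0.51, -4.08 and -1.04. No member passed over all genes or the list alone, and without L5 the adjusted p was 0.536, in a range of 3.09e-06 to 0.645. Hypoxia and glycolysis genes had a median of -0.20 over 23 genes (camera, adjusted p = 0.0242; adjusted p = 0.636 with an estimated correlation). By line it was 0.09 in EGFP, in the other direction, -0.44 in L5 and -0.37 in LacZ. Here 5 passed when adjusted over the list alone and 0 over all genes, among them the collagen prolyl hydroxylase gene P4ha1 (-0.88 ± 0.14) and the glycolytic genes Pfkl (-0.66 ± 0.13) and Aldoa (-0.67 ± 0.15). The adjusted p was 0.139 without L5 and 0.157 without LacZ, in a range of 0.000369 to 0.636.

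Extracellular matrix and adhesion genes had a median of -0.19 over 30 genes (camera, adjusted p = 0.0257; adjusted p = 0.636 with an estimated correlation), and the fibronectin gene Fn1 (-0.90 ± 0.14) was the 1 member that passed when adjusted over the list alone. The adjusted p was 0.265 without LacZ and 0.504 without chromosomes 1, 8, 11 and 14, in a range of 0.0138 to 0.636. It also missed the threshold over every named probe set (0.0720) and with the mean of a gene's probe sets (0.0983), and 6 of 13 alternatives called it. Trophoblast giant cell markers had a median of -0.25 over 14 genes (camera, adjusted p = 0.0305; adjusted p = 0.636 with an estimated correlation), with the VEGF receptor gene Flt1 (-0.68 ± 0.14) as the 1 member that passed when adjusted over the list alone. Of the 22 markers listed, Prl3d1, Prl3d2, Prl3d3, Prl2c2, Prl2c3, Prl2c5 and Prl3b1 were among those that could not be measured. No change in giant cell identity is read from this list. Without L5 its adjusted p by camera was 0.704, in a range of 0.00069 to 0.704. FGF and ERK target genes had a median of -0.22 over 20 genes (camera, adjusted p = 0.0312; adjusted p = 0.645 with an estimated correlation), and 0 passed over all genes or over the list alone. Medians were -0.32 in EGFP, 0.19 in L5 and -0.58 in LacZ, and without LacZ camera gave the other direction (adjusted p = 0.987, in a range of 2.66e-05 to 0.987). Without chromosomes 1, 8, 11 and 14 the giant cell list (adjusted p = 0.0583) and the FGF and ERK list (adjusted p = 0.0668) missed the threshold too, and the latter also with a filter at the 25th percentile of mean signal (0.0647). With genes above the median signal alone, these 2 and the matrix, hypoxia and metal lists missed it, at adjusted p from 0.0626 to 0.0985. By fry 1 of the 12 lists passed, that of fatty acid synthesis.

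The other 15 lists had adjusted p between 0.0833 and 0.999 by camera. Markers of other cells that the cultures could hold were among them. Fibroblast markers had a median of -0.07 (adjusted p = 0.471), embryonic stem cell markers 0.02 (0.706) and primitive endoderm markers 0.00295. In the endoderm list Amn (1.26 ± 0.15), Dab2 (1.17 ± 0.20) and Foxq1 were higher and Thbd (-0.80 ± 0.14) was lower when adjusted over the list alone. Spongiotrophoblast markers had a median of -0.06 and syncytiotrophoblast markers 0.10, the latter without Gcm1 and Syna, which were unnamed here. Targets of TGF-beta (0.04), BMP (-0.00316) and Wnt (0.03) gave no call, and Id3, a BMP target, passed when adjusted over the list alone (-1.98 ± 0.39). Epithelial-mesenchymal transition genes (0.02), p53 targets (-0.05), imprinted genes (0.00686), retinoid and steroid response genes (0.06), sex-linked genes (0.12) and ribosomal proteins (0.02) gave none either. The p53 medians were 0.19 in EGFP, -0.56 in L5 and 0.11 in LacZ. Of 13 alternatives, 1 called the p53 list, that without EGFP (camera, adjusted p = 0.0185). Single members that passed when adjusted over the list alone were Ltbp1 (1.10 ± 0.17) among TGF-beta targets, Col5a1 (0.73 ± 0.12) among fibroblast markers and Cdkn1c (-0.71 ± 0.13) among imprinted genes, as well as Fn1 and Xist (-0.52 ± 0.12). Other probe sets of Col5a1 gave 0.24 and 0.10, and neither was higher in all 3 lines. Other probe sets of Xist gave -1.05 and -0.34, the latter with a rise in L5 from 4.88 to 5.25. The L5 values of Xist, 6.07 and 5.62, were not shown to exceed background. The Y-linked Eif2s3y also passed, but its values of 2.17 to 3.05 were near the floor on all 6 arrays, and no change is read from it. The epithelial-mesenchymal, Wnt and imprinted lists had a median and a mean or a test of different sign.

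Control probe sets for RNA quality were compared between media. For Actb the 3' signal exceeded the 5' signal by 0.60 to 0.70 (log2) in TS and by 0.73 to 0.94 in TX, and it was higher in TX in 3 of 3 lines, in LacZ by the step from 0.70 to 0.73 alone. Gapdh did not follow the medium, with an excess of 0.55 in EGFP in TX, between 0.0096 and 0.14 on the other 5 arrays, and a lower value in TX in LacZ.

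Between the cell lines, 2 genes passed the F test. Xist, the RNA that silences an X chromosome, was lower in L5 than in EGFP by -5.16 ± 0.15 (log2, SE, limma adjusted p = 0.00203). Its values in L5, 6.07 and 5.62, were near the array median and not shown to exceed background, and its 3 probe sets put L5 below the mean of the other lines by -4.87 to -6.29, so the size of this difference is uncertain. Cstf2t, a gene of mRNA cleavage, was higher in L5 than in EGFP by 7.01 ± 0.26 (adjusted p = 0.00397), with values of 10.12 and 9.83 in L5 against at most 3.96 on the other 4 arrays. Those 4 values are in the range of dim probe sets, so this size is uncertain too. Cstf2t did not pass the F test without either array of L5 or with genes above the median signal alone, and Xist did not pass without the TS array of L5. Pair by pair, 7 genes passed between L5 and EGFP, 3 between LacZ and L5 and 0 between LacZ and EGFP, where 2279 had an unadjusted p under 0.05 by limma and 23 passed with an intensity trend and robust moderation. The 3 genes were Xist, Cstf2t and 5730507C01Rik, the last named after its values were seen. With 1 array left out, the count between L5 and EGFP was 2 (TS array of EGFP, or either array of LacZ), 3 (either array of L5) or 8 (TX array of EGFP). The count between LacZ and L5 was 1 without the TS array of L5, and 2 or 3 otherwise. Over every named probe set both counts were 23, and above the median signal both were 1. Between LacZ and EGFP 10 genes passed without the TX array of EGFP and 8 without either array of L5. The F test gave 0 genes without the TS array of L5, 7 without the TX array of EGFP and 52 with an intensity trend and robust moderation.

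Of 81 tests of a list in a pair of lines, 2 passed. Cholesterol genes were higher in L5 than in EGFP (median 0.33, camera adjusted p = 0.00437), and ATF4 response genes were lower in LacZ than in EGFP (median -0.47, adjusted p = 0.0267). By medium, the cholesterol median was 0.43 in TS and 0.12 in TX, and the ATF4 median was -0.89 in TS and -0.14 in TX. Each of these values compares 1 array with 1 array, so a difference between media was not tested. With an estimated correlation 0 of the 81 passed (adjusted p = 0.957 with an estimated correlation for both).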

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

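Stem cell genes whose response to the medium had opposite signs between lines, by at least the residual SD of a difference in 1 line (0.373), were singled out. Eomes differed by 0.4332 in EGFP, 0.5233 in L5 and -0.4233 in LacZ, and Esrrb by -0.2479, 0.5045 and -0.6921. Each line had 1 array per medium, so these differences between lines were not tested. Among 10143 probe sets with no single gene name, 0 passed adjusted p 0.05 by limma. Groups of 3 arrays were not searched for outlying samples.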

How the results depend on the processing

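The alternatives were chosen before the data were examined, except leaving out chromosomes 1, 8, 11 and 14, which was chosen after seeing them. RMA values carry no detection call, so what signal over background limits was examined only through the filters on mean signal. The count of genes changed by medium was 45 with a filter at the 25th percentile of mean signal, 11 with one at the median, 44 over every named probe set, 47 with the mean of a gene's probe sets, 90 with an intensity trend and robust moderation, 98 at adjusted p under 0.1, and 0 to 34 when a line was left out. It was 0 to 17 when a single array was left out together with the line block, and that range does not separate the array from the block. With no replicate block for the line it was 11, of which 9 were among the 24. Filters test fewer genes, and the cause of the other moves was not tested. Genes changed at least 2-fold in every line numbered 47 above the median signal, 329 at 1.5-fold, 338 by a mean 2-fold change in one direction, and 151 to 214 with 1 line left out, where fewer lines have to pass. Genes differing between lines numbered 1 above the median signal, 30 over every probe set, 15 with the mean of probe sets, 52 with trend and robust moderation, and 0 to 7 with 1 array left out.

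Lists shifted by medium numbered 7 above the median signal, 0 with an estimated correlation and 1 by fry, and 9 to 13 with 1 line left out. The cholesterol median of 1.04 lost its call with an estimated correlation and by fry, and the fatty acid median of 0.78 with an estimated correlation. The stem cell list gained a call over every probe set (-0.137) and with the mean of probe sets (-0.135), and ran from -0.184 to -0.0295 with 1 line left out, with a call without EGFP and without L5. List shifts between lines numbered 14 over every probe set and 0 with an estimated correlation. Mean r fell with filters, to 0.968 for both arrays of one line and of one medium at the 25th percentile, and to 0.944 and 0.942 at the median.

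Changes near 0 turned sign. With the mean of probe sets Elf5 was at -0.018 and Tfap2c at -0.046. With a line left out, or an array left out together with the line block, Eomes ran from -0.092 to 0.48, Elf5 from -0.062 to 0.30, Esrrb from -0.50 to 0.21, Tfap2c from -0.070 to 0.20 and Fgfr2 from -0.044 to 0.27. The FGF and ERK list ran from -0.30 to -0.10, and camera's direction turned without LacZ. The cause was not tested.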

Other observations

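The tests of the placement of genes on chromosomes, of single lines, of whole-chromosome copy number for chromosomes 8 and 14, 1 and 11, and of male cells were chosen only after the results were seen. Some genes of the germline had higher values in TX medium. Besides Meioc and Syce1, which passed the threshold, these were Ddx4, a helicase of germ cells, at 2.88 ± 0.46 (log2, SE), Mael at 2.57 ± 0.43, Slc25a31 at 2.31 ± 0.23 and the RNA-binding gene Dazl at 2.30 ± 0.22, and these 4 missed the threshold (limma, adjusted p from 0.0515 to 0.115). They were singled out after their values were seen, and some of their TS values, down to 2.60 for Slc25a31, were in the range of dim probe sets, so the sizes are uncertain. A list of 47 other germline genes had a median of 0.17, with 17 higher and 4 lower in all 3 lines, and its call was lost with an estimated correlation (adjusted p = 0.153). It included Sycp1 (1.29 ± 0.35), a gene of the synaptonemal complex, and Rhox13 (1.24 ± 0.16), and 0 passed over all genes.

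Noise of dim probe sets is argued against by a permutation test, in which lists matched on mean signal reached such a median at p = 1e-04, the smallest that 10000 lists can give. The rise was not that of one line, since the median stayed at 0.168 or more with any line left out. A wider rise of germline genes with the medium may be a candidate explanation, with camera p = 0.000425, and p = 0.051 with an estimated correlation. Such a rise stays a hypothesis, found and tested on the same arrays. Lysosome genes other than Ctsa, Ctsh and Npl had a median of 0.07 (camera, adjusted p = 0.529 over the 3 added lists), and macrophage markers one of -0.03 (adjusted p = 0.529).

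Genes of some chromosomes differed as a group between arrays. Over 9080 genes above the median signal, chromosome 14 was higher in L5 than in EGFP in TS (median 0.38, 1.30-fold) but not in TX (0.01), and within L5 it was lower in TX than in TS by -0.39. Chromosome 8 was higher in L5 than in EGFP in both media (0.36 and 0.32). Chromosome 1 was lower in L5 and LacZ than in EGFP in TS (-0.30 and -0.22), and chromosome 11 lower in L5 than in EGFP (-0.20 in TS and -0.30 in TX).

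Chance placement of genes is argued against by a permutation p = 0.001, the smallest that 1000 shuffles can give, a trend with signal level by medians that kept at least 97.26% of their size after a loess fit, and a few strongly changed genes by at least 69.2% of genes on the shifted side. Among 12 differences of at least 0.15, a limit set after seeing the data, 10 had all 4 equal blocks of the genes, in annotated order, on the shifted side. With block medians taken as positive on the side of the chromosome's own shift, every block of chromosomes 8 and 14 was shifted, by at least 0.149, and an extra copy in part or all of the L5 cells may explain this, for chromosome 14 in the TS culture only. For chromosome 1 the first block lay on the opposite side of 0 (-0.0542 by that sign), which argues against a change of the whole chromosome. For chromosome 11 the smallest block median, on the shifted side, was 0.0191, and whole and partial changes cannot be told apart, because in 2 of its 3 differences a block lay within the spread of the other chromosomes.

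Xist was low in L5 on all 3 of its probe sets, by -4.87 at the least, which argues against a failed probe set. Male cells in L5 could not be decided on: the 9 probe sets of the Y-linked genes Eif2s3y, Kdm5d and Uty were at most 0.258 higher in L5 than in the other lines, but stayed at or below 4.97 on all 6 arrays, so no array showed that they detect their genes. Chromosome X was among the 20 chromosomes compared, and none of the 12 differences of at least 0.15 was on it. Its genes thus showed no group difference of that size between L5 and the other lines. Beyond this, a loss of an X chromosome or of its silencing in L5 was not tested.

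Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. Of these 1, the real one, gave as many genes, with 24 against at most 2 in the others, and 1 gave as many lists, with 12 against at most 10. Among the 4 splits that part all 3 lines, as the media do, the highest other values were 0 genes and 9 lists. The other 6 splits part 1 line only, so with the line as a block each compares the TS and TX arrays of that line alone, and the values of 2 genes and 10 lists come from such splits.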
